A study of Saccharomyces cerevisiae BY4741 with 4 samples.

How the data were processed

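Cells of Saccharomyces cerevisiae BY4741 were grown in YPD medium at 30 °C from an OD600 of 0.05 to 0.6 in 100 mL, and RNA was extracted from 10 mL with hot acidic phenol, per the labels. Poly(A) RNA was selected on oligo-dT beads and then depleted of rRNA with a commercial kit, per the labels' protocols. Libraries were made from 50 ng of RNA with random hexamers and 14 cycles of PCR and sequenced single-end at 50 bases. The kit's name does not state a strand-marking step in the labels.

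The deposited table holds raw whole-number read counts per annotated feature, 1 column per library, per the file headers and the values. FastQC 0.11.8, cutadapt 1.18, Bowtie2 2.3.4.3 and genome build R64 are named in the submitters' processing notes, without their roles. The counting program, its use of strand and its treatment of reads that match several places were not given in the sources used here. Of the 7382 features, 622 are joined names, which hold reads where the named features overlap, among them genes on opposite strands. Reads of overlapping genes, antisense pairs and near-identical paralogs are therefore uncertain. A further 5 lines of the table were empty. No line had 0 counts in all 4 libraries, since the lowest sum was 1, so a gene without a line cannot be told apart from one without reads. All columns were matched to a sample.

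Of 6760 single features, 6010 matched the RefSeq reference of build R64 by locus tag or name, and coordinates and lengths were taken from there. RNA classes came from the biotype in that reference and otherwise from name patterns. A joined feature with an rRNA member was counted as rRNA. Of 6433 single nuclear reading frames, 556 had no entry in the reference and so no length.

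Shares of counts were compared with an exact two-sided permutation test, whose smallest p with 2 against 2 libraries is 0.333. Differences per feature were tested with edgeR 4.0.16 (R 4.3.3) on the deposited counts, with filterByExpr, TMM normalisation, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The TMM factors were 0.162 and 0.156 for total RNA replicates 1 and 2 and 6.25 and 6.34 for the poly(A) replicates. The SE of a log2 fold change was its size divided by the square root of F. The square root of the common dispersion was 0.0612. Normalised values are TMM-normalised CPM, counts scaled to a common effective library size. The labels call the libraries biological replicates and do not say whether replicate numbers link the fractions, so no block was used.

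Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted by Benjamini-Hochberg over 14 lists. The lists were cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis factors, translation factors, RNA modification enzymes, poly(A) tail enzymes and binding proteins, core histones and H1, glycolysis and fermentation, oxidative phosphorylation, ergosterol synthesis, cell wall proteins, heat shock and chaperones, a-cell markers and alpha-cell markers. The auxotrophy markers had 1 tested member and got values only.

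The tests, the lists, the alternatives in the closing section unless said otherwise, and the rule for named genes were fixed before the data were examined. The rule took, among features past the test with a mean of at least 10 normalised CPM and both poly(A) libraries on the same side of both total RNA libraries, the 8 coding features with the largest and the 8 with the smallest log2 fold change and the 4 largest and 4 smallest of all other classes. It also took up to 3 members of each list with the largest absolute log2 fold change, whatever their p, the 6 features with most counts in each fraction, and the 4 auxotrophy markers.

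For a feature with 0 counts in a fraction, the fold was bounded with a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with an exact 95% interval from the binomial distribution of the counts. These folds used TMM effective library sizes, so they differ from the plain ratio of the counts. PCR reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. Bootstrap intervals used 1000 draws of genes. The share of 50-base stretches of a gene found elsewhere in the reference genome, on either strand, was computed as a measure of reads that could match several places.

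The edgeR procedure was tested on simulated counts for the comparison of poly(A) with total RNA, with 6772 coding features and 200 of them changed. It called 87% of the features changed 2-fold, 64.6% of those changed 1.5-fold and 0.139% of the unchanged ones. The simulated counts held no rRNA, and increases and decreases were equal in number, so the scaling between fractions was not tested. The composition and length analyses used Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6. Alternatives were DESeq2 size factors and the DESeq2 1.42.0 Wald test, library totals, coding features only, other filters, a replicate block, a 2-fold minimum with glmTreat, and leaving out each library.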

Results

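RNA was measured in exponentially growing cells of BY4741, a haploid laboratory strain of the budding yeast Saccharomyces cerevisiae. Total RNA and poly(A) RNA were each sequenced in 2 biological replicates, per the labels, and the deposited table gave read counts for 7382 annotated features. The series concerns modified nucleosides in yeast mRNA, for which the composition of the purified mRNA fraction matters. The poly(A) RNA had been purified on oligo-dT beads and then depleted of rRNA with a commercial kit. Total RNA replicates 1 and 2 held 53746838 and 75955489 counts, and poly(A) replicates 1 and 2 held 52851542 and 53180654. Only 1689024 and 2388992 of the total RNA counts fell on nuclear protein-coding features, against 52729043 and 53055238 of the poly(A) counts. The median coding feature therefore had 62 and 85 counts in the total RNA libraries and 2459 and 2465 in the poly(A) libraries, so the total RNA libraries set the precision of most comparisons of mRNAs.

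The first comparison asked which RNA classes each fraction contained. Nuclear rRNA, the RNA of the cytosolic ribosome with its transcribed spacers, made up 96.4% ± 0.0272 (SD, n = 2) of the counts in total RNA and 0.0488% ± 3.51e-05 (SD, n = 2) in poly(A) RNA, a share 1974-fold lower. Nuclear protein-coding features rose from a share of 3.14% ± 0.00191 in total RNA to 99.8% ± 0.00286 in poly(A) RNA, which is 31.7-fold. Small nucleolar RNAs, which guide rRNA processing and modification, held 0.142% ± 0.0111 of total RNA counts and 0.0624% ± 0.00181 of poly(A) counts. Spliceosomal snRNAs held 0.0787% ± 0.0103 and 0.0104% ± 0.000573. The class of stable structured RNAs, which holds the signal recognition particle RNA SCR1 and the RNA subunits of RNase P and RNase MRP, held 0.217% ± 0.00339 and 0.0117% ± 0.000909. Mitochondrial rRNA fell from 0.0244% ± 0.00228 to 0.000259% ± 3.45e-05.

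Other classes did not lose share as a whole. Mitochondrially encoded reading frames held 0.00686% ± 0.000148 of total RNA counts and 0.00821% ± 0.000528 of poly(A) counts. A single gene of this class, OLI1, chosen after its values were seen, carried 3488 of its 4538 and 3257 of its 4169 poly(A) counts, but 262 of 3745 and 379 of 5134 total RNA counts, so the other reading frames lost share. Long noncoding RNAs held 0.000692% ± 2.87e-05 and 0.0375% ± 0.000405, and pseudogenes 0.000311% ± 1.22e-05 and 0.00871% ± 0.000598. The long noncoding RNAs RUF5-1 and RUF5-2 carried 6155 and 6030 of the 19654 poly(A) counts of their class in replicate 1. In total RNA replicate 1 they carried 76 and 63 of 361. Nuclear tRNAs were nearly absent from both fractions, at 0.000107% ± 2.26e-05 and 0.00151% ± 5.34e-05, so their abundance was not measured by these libraries. For each of these 10 classes both poly(A) libraries lay on the same side of both total RNA libraries. The exact two-sided permutation p was 0.333 for each, which is the smallest p that the 6 labelings of 2 against 2 libraries allow. The difference between fractions exceeded the spread between replicates in every one of these classes, but the design cannot reach a smaller p for a single share.

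**Figure D1:**
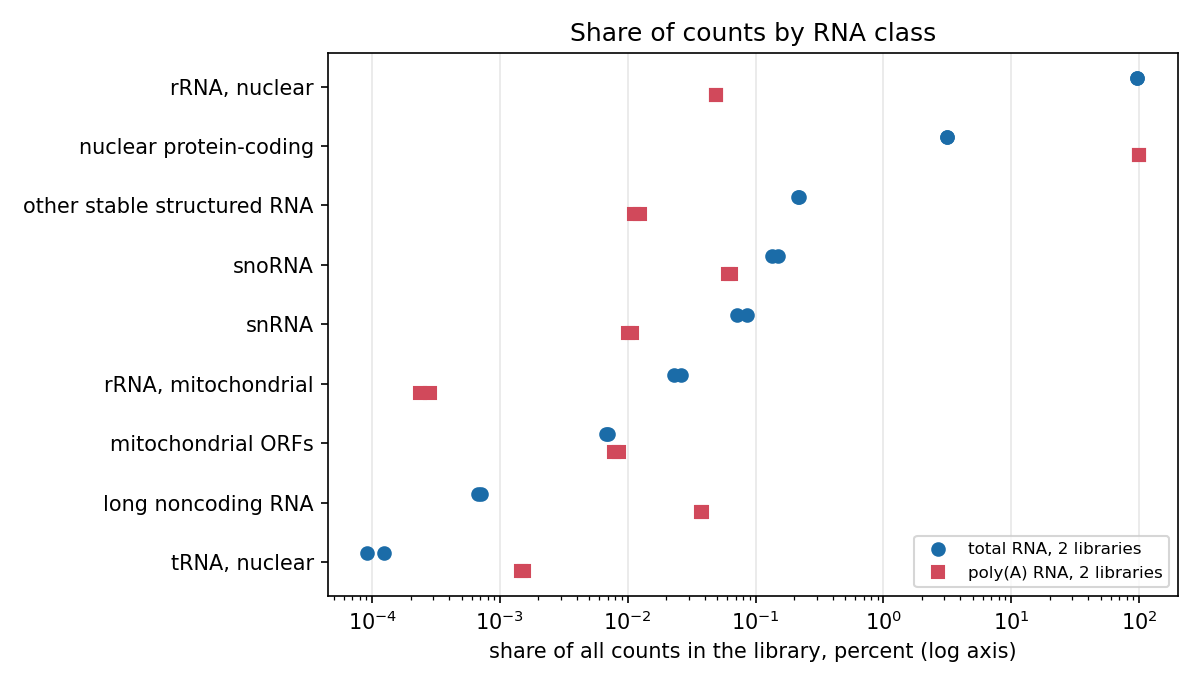
Share of all counts in each library (percent, log axis) by RNA class; circles are the 2 total RNA libraries and squares the 2 poly(A) libraries. Nuclear rRNA lies at 96.4% in total RNA and 0.0488% in poly(A) RNA, and nuclear protein-coding features at 3.14% and 99.8%.

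The second comparison asked whether individual transcripts kept their relative abundance through poly(A) purification. All log2 fold changes are poly(A) against total RNA and relative to the typical feature after TMM normalisation, so they describe relative abundance, not RNA per cell. Of 6945 features tested, 2153 were higher and 2164 lower in poly(A) RNA at an adjusted p under 0.05, and 2628 did not pass. Among the 6772 nuclear protein-coding features, 2143 were higher and 2047 lower. In a stricter test against a 2-fold change, the count of genes higher in poly(A) RNA was 98 and that of genes lower in poly(A) RNA was 737. By fold change alone, 531 of the features past the test were higher by more than 2-fold and 1082 lower. All these counts depend on where the scaling puts zero. All 19 mitochondrial reading frames tested were lower, as were 26 of 28 nuclear rRNA features, both mitochondrial rRNAs, 4 of 4 snRNA features, 3 of 3 stable structured RNAs and 47 of 71 snoRNAs. None of these 6 classes had a feature that was higher. Of 12 long noncoding RNAs tested, 4 were higher and 5 lower, with a median log2 fold change of -0.40.

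The position of zero depended on the scaling. With library totals and no TMM, the median log2 fold change of all tested features moved from 0.044 to 5.34 and the share of calls that were higher from 49.9% to 98.9%. With scaling to the sum of the nuclear protein-coding counts, an alternative added after the data were seen, the median was 0.37 and that share 67.1%. Directions below are relative to the typical feature. Under library totals the decreases of named coding genes became increases, except for YLR154W-E, YLR154W-F and RRT15, which stayed lower, and FLO11, which had -0.14 and did not pass.

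Of the coding features that were higher, 8 with at least 10 normalised CPM had the largest fold changes, and both poly(A) libraries lay above both total RNA libraries in each by the rule of selection. RPP1A, a stalk protein of the large ribosomal subunit (chromosome IV, 309802 to 310122), rose from 141.2 ± 9.24 to 434 ± 30.1 TMM-normalised CPM (SD, n = 2), a log2 fold change of 1.62 (SE 0.08, adjusted p = 1.31e-13). RPL43B, another large-subunit protein, rose by 1.53 (SE 0.09, adjusted p = 3.73e-12). The feature that joins RPL39 with the overlapping YJL188C had the highest value of these 8, 1.70 (SE 0.12), and the one that joins RPS27A with YKL156C-A had 1.55 (SE 0.13). TOA2, the small subunit of transcription factor TFIIA, rose by 1.61 (SE 0.14). HOR7, known for its response to high osmolarity, rose by 1.61 (SE 0.12), and SEM1, a component of the proteasome lid, by 1.53 (SE 0.12). YKL066W, a reading frame without an entry in the reference used here, completed the 8 at 1.59 (SE 0.14).

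The coding features that were lowest fell into 2 groups. YLR154W-E, YLR154W-F and RRT15 lie in or resemble the rDNA on chromosome XII. YLR154W-E had 678 and 974 counts in total RNA and 0 in both poly(A) libraries. After TMM normalisation that was at least 17890-fold lower, with a floor of 3 counts over the group. YLR154W-F had 611 counts in total RNA and 1 in poly(A) RNA, a 19850-fold difference after TMM normalisation (95% counting interval 3549 to 785200). RRT15 (490406 to 490594) had 35400 and 49376 counts against 9 and 17, a log2 fold change of -16.66 (SE 0.16). Of the 50-base stretches of RRT15, 4.29% also occur in the rDNA, and reads from that part cannot be assigned with certainty. How many of its reads came from there was not examined. The others were mRNAs of genes between 1815 and 5202 bp. FLO11, a cell surface flocculin with 28.0% of its 50-base stretches found elsewhere, had a log2 fold change of -5.45 (SE 0.14, adjusted p = 1e-18). DED1, an RNA helicase of translation initiation, fell from 185.6 ± 8.50 to 7.23 ± 0.00324 normalised CPM, a log2 fold change of -4.68 (SE 0.09, adjusted p = 1.57e-21). AGA1, the anchoring subunit of a-agglutinin, RPO21, the largest subunit of RNA polymerase II, and PUF3, an RNA-binding regulator of mRNAs for mitochondrial proteins, had log2 fold changes of -4.26, -4.17 and -4.12 (SE 0.09, 0.09 and 0.10).

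Outside the coding features, the largest increases among features past the test with a mean of at least 10 normalised CPM came from the duplicated CUP1 locus on chromosome VIII. The noncoding RNAs RUF5-1 and RUF5-2 rose by 1.15 and 1.14 (SE 0.12 and 0.13), and the 2 features that join them with the metallothionein genes CUP1-1 and CUP1-2 rose by 1.10 and 1.38 (SE 0.12 for both). All 50-base stretches of both RUF5 copies occur elsewhere in the genome, and the strand was not stated for the counting, so the copies and the overlapping CUP1 genes were not told apart. The largest decreases were in rRNA. The internal transcribed spacer ITS2-2 had a log2 fold change of -17.31 (SE 0.16), with 13275 and 19198 counts in total RNA and 3 in each poly(A) library. The joined features of the 35S precursor with 18S rRNA, RDN37-1--RDN18-1 and RDN37-2--RDN18-2, had -16.88 and -16.90 (SE 0.16 for both). RDN37-1--RDN25-1--YLR154W-C, part of 25S rRNA, had -16.84 (SE 0.16). The 18S features alone carried 25.4% and 25.5% of all total RNA counts, and the 25S features RDN37-2--RDN25-2 and RDN37-1--RDN25-1 22.0% and 17.4%.

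Ribosomal protein genes were higher as groups. Of 134 cytosolic ribosomal protein genes tested, 108 were higher and 9 lower, and the counts adjusted over the list alone were also 108 and 9. The median log2 fold change was 0.81 (camera adjusted p = 4.23e-21), with adjusted p = 0.318 with an estimated correlation. RPP1A, RPL43B and RPS31, a ribosomal protein made as a ubiquitin fusion, lay furthest from 0, RPS31 at 1.52 (SE 0.08). In the 54 members without any 50-base stretch found elsewhere in the genome, 42 were higher and 6 lower, with a median of 0.77. Of 56 mitochondrial ribosomal protein genes, 47 were higher and 2 lower (48 and 2 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 3.47e-08; adjusted p = 0.318 with an estimated correlation). MRPL38 had 2 counts in total RNA and 534 in poly(A) RNA, an 8.22-fold difference after TMM normalisation (95% counting interval 2.26 to 68.0). MRPS16 and MRP35 rose by 1.46 and 1.40 (SE 0.18 and 0.28).

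Core histone genes and H1 showed 6 of 9 members higher and 0 lower, also adjusted over the list alone, with a median of 0.77 (camera adjusted p = 0.00583; adjusted p = 0.318 with an estimated correlation). HTA1, HHF1 and HHT1, encoding histones H2A, H4 and H3, rose by 1.17, 1.02 and 0.87 (SE 0.08, 0.08 and 0.09). Each of these genes shares sequence with its paralog, and in the 3 members without shared 50-base stretches 0 passed the test and the median was -0.028. Subunits from the list of nuclear-encoded oxidative phosphorylation were higher in 18 of 33 genes and lower in 5, the same counts as adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.0172; adjusted p = 0.318 with an estimated correlation). QCR9 and QCR7 of the cytochrome bc1 complex and CYC1, which encodes cytochrome c, rose by 1.74, 1.32 and 1.48 (SE 0.22, 0.11 and 0.22). The list did not pass without total RNA replicate 2 (median 0.37), with a replicate block (0.41), with at least 10 CPM in 2 libraries (0.51) or under scaling to the coding sum (0.73), and its median turned to -0.076 when the trend with gene length was removed.

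Cell wall protein genes were lower throughout. All 17 were lower, also adjusted over the list alone, with a median of -1.19 (camera adjusted p = 1.82e-10; adjusted p = 0.318 with an estimated correlation). FKS1, a catalytic subunit of glucan synthase, the cell wall protein SCW4 and SED1, a mannoprotein of the wall, had log2 fold changes of -3.74, -2.81 and -2.12 (SE 0.08 for each). Glycolysis and fermentation genes were lower in 15 of 20 and higher in 3, the same counts as adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.0156; adjusted p = 0.777 with an estimated correlation). The list of glycolysis and fermentation lost its call under scaling to the coding sum (median -0.033), with at least 10 CPM in 2 libraries (-0.22) and with a replicate block (-0.36). Both phosphofructokinase subunits, PFK2 and PFK1, and the pyruvate kinase CDC19 led this list with log2 fold changes of -2.17, -2.02 and -1.50 (SE 0.08 for each). Genes for poly(A) tail enzymes and binding proteins were lower in 6 of 11 and higher in 0, also adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.0166; adjusted p = 0.383 with an estimated correlation). The list of poly(A) tail enzymes and binding proteins did not pass with at least 10 CPM in 2 libraries (median -0.60). Its median was -0.010 under scaling to the coding sum, -0.22 without poly(A) replicate 2 and -0.73 in the 10 members without shared 50-base stretches. The deadenylase CCR4, its scaffold CDC39 and the deadenylase subunit PAN2 had log2 fold changes of -2.70, -2.67 and -1.52 (SE 0.09, 0.08 and 0.10).

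With an estimated correlation, camera called 0 of the 14 lists. The smallest unadjusted p was then 0.0718, for cell wall proteins, so 0 lists had an unadjusted p under 0.05. The fry test, which does not compare a list with other genes, called 4 lists higher and 5 lower, with translation factors and alpha-cell markers among the lower. Its direction was lower for ribosome biogenesis factors and a-cell markers, whose medians were above 0.

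**Figure D2:**
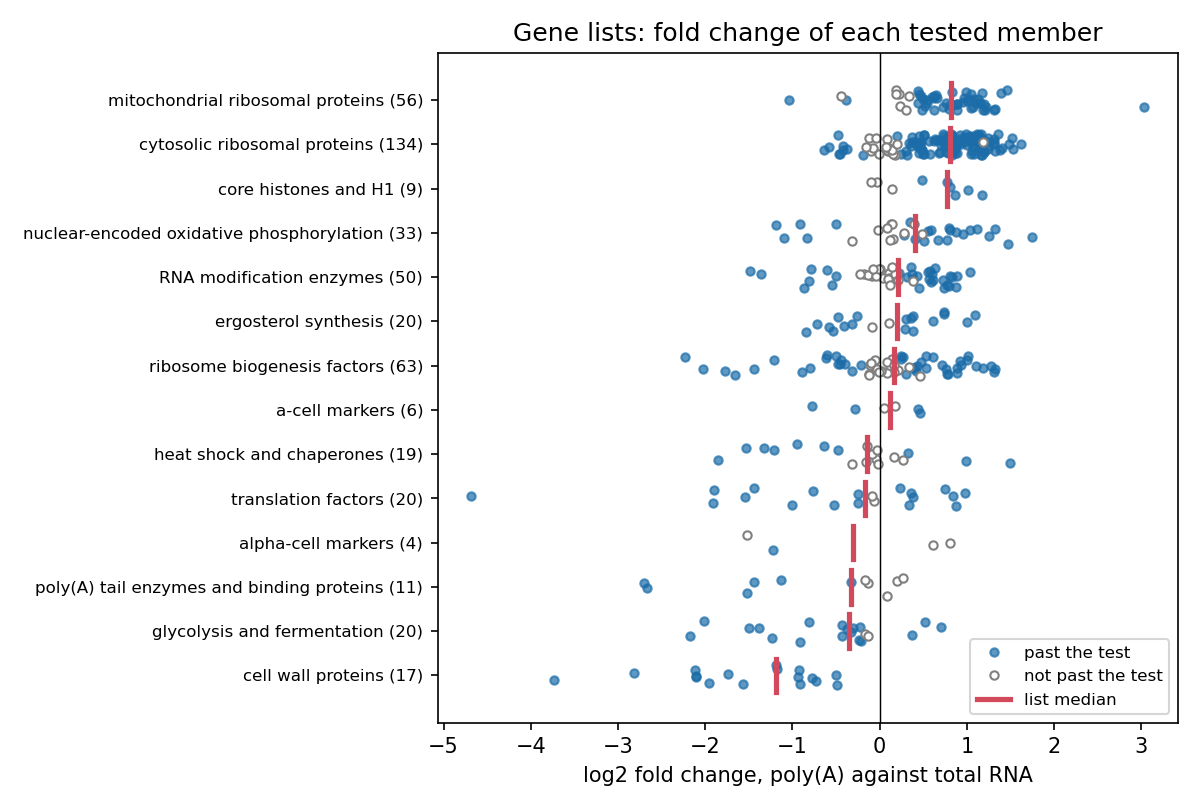
Log2 fold change, poly(A) against total RNA, of each tested member of 14 gene lists (filled where past the test, open where not), with the number tested in brackets and a bar at the list median. Medians range from -1.19 for cell wall proteins to 0.82 for mitochondrial ribosomal proteins.

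The other lists went both ways. Of 50 RNA modification enzyme genes tested, 23 were higher and 8 lower (the same adjusted over the list alone; median 0.21, camera adjusted p = 0.0965), with TRM3 and KRE33 at -1.49 and -1.36 and TAN1 at 1.04. Without poly(A) replicate 1 the list of RNA modification enzymes passed, with a median of 0.33. TRM3 encodes a tRNA ribose methyltransferase and KRE33 an acetyltransferase of rRNA and tRNA that works with TAN1. Ribosome biogenesis factors had 27 higher and 17 lower of 63 (28 and 17 adjusted over the list alone; median 0.16, camera adjusted p = 0.252), and UTP20, RRP14 and UTP10 had -2.23, -2.03 and -1.78. Translation factors had 8 higher and 10 lower of 20 (the same adjusted over the list alone; median -0.17, camera adjusted p = 0.252, but a median of 0.15 for translation factors under scaling to the coding sum and of 0.28 in the 14 members without shared 50-base stretches, 8 higher and 6 lower, and of -0.11 without total RNA replicate 2), led by DED1 and by EFT2 and EFT1, which encode elongation factor 2, at -1.91 and -1.90. Of the 50-base stretches of each EFT gene 91.9% are found elsewhere, so their values are not independent. Ergosterol synthesis genes had 10 higher and 8 lower of 20 (the same adjusted over the list alone; median 0.20, camera adjusted p = 0.509), with ERG28 at 1.10, ERG26 at 1.00 and ERG5 at -0.85. Heat shock and chaperone genes had 3 higher and 7 lower of 19 (the same adjusted over the list alone; median -0.15, camera adjusted p = 0.184, but a median of 0.17 under scaling to the coding sum). SSC1 and SSA2, both Hsp70 chaperones, had -1.85 and -1.54, and HSP12, with only 5 and 6 counts in total RNA, had 1.49. The direction of the list of heat shock and chaperones rested on single libraries: without poly(A) replicate 1 it passed at a median of -0.34, without poly(A) replicate 2 the median was 0.049, and without total RNA replicate 1 it was -0.074. With the trend with length removed it was 0.094.

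BY4741 is of mating type a, so transcripts made only in a cells or only in alpha cells served as a check of identity. STE6, which encodes the a-factor exporter, stood at 119.0 ± 2.95 and 69.6 ± 4.84 normalised CPM in total and poly(A) RNA. Of the 6 a-cell markers 2 were higher and 2 lower (3 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.811, with a median from 0.071 to 0.21 when poly(A) replicate 2 or 1 was left out), with STE6 at -0.77, the a-factor gene MFA1 at 0.46 and AGA2, a subunit of a-agglutinin, at 0.44. With the trend with length removed, these turned to 0.50, -0.098 and -0.091, and the median to -0.036. Among the alpha-cell markers, SAG1, encoding alpha-agglutinin, had 70 and 117 counts in total RNA, and the others were scarcer. The a-cell marker MFA1 had 89 and 142 counts. Its gene is 111 bp long and that of SAG1 1953 bp, so these counts are not comparable as expression levels. STE6, of 3873 bp, had 1018 and 1433. The alpha-factor gene MF(ALPHA)1 had 5 and 1 counts in total RNA and 31 and 37 in poly(A) RNA (log2 fold change -1.52, SE 0.82, adjusted p = 0.116). Leaving out total RNA replicate 2 gave another log2 fold change: MF(ALPHA)1 stood at -2.48 and passed. STE3, the a-factor receptor, had 5 and 6 against 302 and 326 (0.81, SE 0.41, adjusted p = 0.0942). SAG1 was the only one of these 4 to pass, at -1.22 (SE 0.14), and the list had 0 higher and 1 lower, also adjusted over the list alone (median -0.30, camera adjusted p = 0.777, but a median of 0.021 under scaling to the coding sum). The median of the alpha-cell markers was 0.050 without total RNA replicate 1, -0.16 without total RNA replicate 2 and 0.61 in the 3 members without shared 50-base stretches, so it has no settled direction. Of the 4 auxotrophy markers of BY4741, HIS3 had 13.2 ± 1.41 and 15.2 ± 1.47 normalised CPM, a log2 fold change of 0.21 (SE 0.12, adjusted p = 0.134). HIS3 passed without poly(A) replicate 1 (0.35) or total RNA replicate 1 (0.32). LEU2, MET17 and URA3 had no line in the table used here.

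Of the 6 features with most poly(A) counts, 5 differed by less than 0.5 on the log2 scale. FBA1, which encodes aldolase, held 1.96% of poly(A) counts and was higher by 0.37 (SE 0.07, adjusted p = 0.000197). TDH3, a glyceraldehyde-3-phosphate dehydrogenase, held 1.47% and was lower at -0.44 (SE 0.08), and the enolase ENO2 held 1.46% at -0.24 (SE 0.08). TEF1 and TEF2, near-identical genes for elongation factor 1 alpha, held 1.45% and 1.44% at -0.25 each (SE 0.08), with 92.5% of their 50-base stretches shared. Under scaling to the coding sum, ENO2, TEF1 and TEF2 turned to 0.083, 0.068 and 0.067 and TDH3 lost its call at -0.12. ENO2 did not pass without poly(A) replicate 2 (-0.12) or total RNA replicate 2 (-0.19). The feature that joins CDC19 with YAL037C-B held 0.940% at -1.21 (SE 0.08).

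Fold change followed gene length. Over 5772 nuclear coding genes with a length in the reference, Spearman's rho between length and log2 fold change was -0.60 (95% bootstrap interval -0.62 to -0.58). This is a correlation across genes, which are not independent replicates, and reference lengths here include introns but no untranslated regions. The median was 0.61 in 229 genes of up to 300 bp, 0.60 in 811 genes from there to 600 bp and 0.47 in 1826 genes up to 1200 bp. It was -0.11 in 2048 genes up to 2400 bp, -0.88 in 766 genes up to 4800 bp and -1.91 in 92 longer genes. All 92 of the longest genes were lower, and of the 766 genes in the bin before them 655 were lower and 2 higher. The median length was 657 bp for mitochondrial ribosomal proteins, 783 bp for cytosolic ribosomal proteins, 399 bp for histones, 462 bp for oxidative phosphorylation, 978 bp for cell wall proteins, 1386 bp for glycolysis and 1755 bp for the poly(A) tail list.

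**Figure D3:**
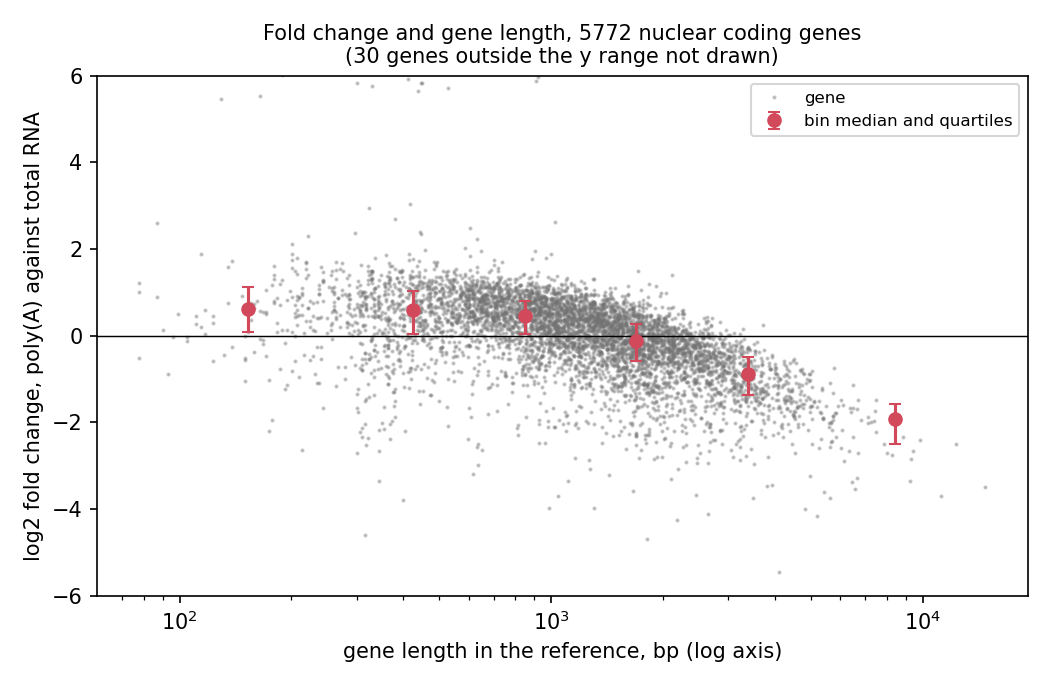
Log2 fold change, poly(A) against total RNA, against gene length in the reference (bp, log axis) for 5772 nuclear coding genes; genes outside the y range are not drawn. Filled circles with bars are bin medians with quartiles, which run from 0.61 in genes of up to 300 bp to -1.91 in genes over 4800 bp.

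With the trend with length taken out, an adjustment chosen after the data were seen, cell wall proteins kept a lower median of -1.70 (camera adjusted p = 2.72e-41; adjusted p = 0.148 with an estimated correlation). Cytosolic ribosomal proteins kept a higher median of 0.39 (camera adjusted p = 1.86e-05, and adjusted p = 0.886 with an estimated correlation). The lengths used include introns, so for genes with introns the mRNA length was overstated and the correction may be off. Glycolysis kept a lower median of -0.48 (camera adjusted p = 3.71e-05; adjusted p = 0.886 with an estimated correlation), and translation factors passed at -0.20 (camera adjusted p = 0.000969; adjusted p = 0.830 with an estimated correlation). That call includes members with shared sequence, and without them the median before removal of the trend was 0.28. Mitochondrial ribosomal proteins (median 0.41, camera adjusted p = 0.0514), histones (0.24, adjusted p = 0.769) and poly(A) tail genes (-0.17, adjusted p = 0.0514) no longer passed. Among 5747 genes tested this way, the count of genes lower in poly(A) RNA was 1340 and that of genes higher in poly(A) RNA was 1854, so 58.0% of calls were higher.

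The spread between replicates was larger in total RNA than in poly(A) RNA. The SD of the log2 difference between replicates over the 6945 tested features was 0.17 for poly(A) RNA and 0.84 for total RNA, where most features had few counts. Among features with at least 10 CPM in 2 libraries the gap was much smaller, as given in the closing section. Across features, which are not independent replicates, Pearson's r was 0.998 and 0.959 and Spearman's rho 0.998 and 0.990. Replicates differed by more than counting error, with a mean chi-square per gene of 28.4 for poly(A) RNA and 1.89 for total RNA, so no library had been entered a second time.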

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

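Merging joined features, removing the length trend, dropping nuclear rRNA features, scaling to the coding sum and the submitters' own RNA species column were chosen after the results were seen; the rest were planned. Depth of total RNA limits most values, since the median coding feature had 62 and 85 counts. When a library was left out, genes higher in poly(A) RNA numbered 1841 to 2085 and genes lower in poly(A) RNA 1891 to 2072, the lone library being assumed to vary like the other fraction, and 3 to 5 lists were called higher and 3 to 4 lower. DESeq2 size factors gave 2052 and 2193 and the Wald test 1829 and 2092. Same-numbered deviations of the fractions had a correlation of 0.031. That value cannot decide whether replicate numbers pair the fractions, since counting error was a large part of the differences in total RNA. A fit with replicate number as a block gave 2200 higher and 2191 lower, with 3 and 2 lists. Library totals gave 6860 higher and 75 lower, 9 lists higher and 0 lower. At least 10 CPM in 2 libraries gave 1390, 1350 and 1 list lower, from fewer genes tested, and a 2-fold minimum 98 and 737. Removing the length trend gave 1340 lower and 1 list higher, and scaling to the coding sum 3131 and 1535. An estimated correlation called 0 lists either way (0 at an unadjusted p under 0.05), and fry 5 lower. At 10 CPM the replicate spread, SD of log2 difference, total RNA, was 0.198, and the replicate spread, SD of log2 difference, poly(A) RNA, was 0.132, from fewer features.

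Under library totals, which leave the rRNA in the denominator, these log2 values turned from negative to positive: the medians of cell wall proteins 4.12, glycolysis and fermentation 4.96, poly(A) tail enzymes and binding proteins 4.98, translation factors 5.14, heat shock and chaperones 5.16 and alpha-cell markers 4.96, and DED1 0.63, AGA1 1.04, RPO21 1.14, PUF3 1.19, STE6 4.54, MF(ALPHA)1 3.73, SAG1 4.09, FKS1 1.57, SCW4 2.497, SED1 3.19, ERG5 4.46, PFK2 3.14, PFK1 3.29, CDC19 3.81, SSC1 3.46, SSA2 3.77, CCR4 2.61, CDC39 2.64, PAN2 3.79, UTP20 3.08, RRP14 3.28, UTP10 3.53, TRM3 3.82, KRE33 3.95, EFT2 3.40, EFT1 3.41, TDH3 4.87, ENO2 5.07, TEF1 5.06, TEF2 5.06 and YAL038W--YAL037C-B 4.10. Scaling to the coding sum turned ENO2 to 0.083, TEF1 to 0.068, TEF2 to 0.067 and the medians of translation factors to 0.15, heat shock and chaperones to 0.17 and alpha-cell markers to 0.021. With the length trend removed, nuclear-encoded oxidative phosphorylation turned to -0.076, STE6 to 0.50, MFA1 to -0.098 and AGA2 to -0.091; the cause was not tested beyond length.

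Outside nuclear rRNA, whose removal from the total raises every other share, shares of total RNA were 86.7% for nuclear protein-coding features, 5.99% for other stable structured RNA, 3.92% for snoRNA, 2.17% for snRNA, 0.674% for mitochondrial rRNA, 0.279% for joined features of different classes, 0.189% for mitochondrially encoded open reading frames, 0.0191% for long noncoding RNA, 0.00859% for pseudogene, 0.00294% for nuclear tRNA and 2.55e-05% for mitochondrial tRNA, which rests on 1 count in total RNA replicate 1 and 0 in replicate 2, and coding features were 99.81% of poly(A) RNA. Name patterns gave 99.77% for the latter. The submitters' species column gave 3.15% and 99.78% for coding features, 0.216% and 0.0489% for noncoding RNA and 0.0491% for rRNA in poly(A) RNA. The counts are the same, and only the assignment of features to classes differs. With the submitters' noncoding class, the rise of long noncoding RNA turned to a fall. Its share of total RNA lay near the 0.217% of stable structured RNA here.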

Other observations

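All tests in this part were chosen after the results were seen, and the RNAs it singles out were chosen after their values were seen. Small nucleolar RNAs split by size. Of 36 snoRNAs over 150 bases, 35 were lower in poly(A) RNA with a median log2 fold change of -5.72, and of 35 snoRNAs of up to 150 bases 12 were lower with a median of -0.71. Across 71 snoRNAs Spearman's rho of length and fold change was -0.74 (95% bootstrap interval -0.84 to -0.59). The small ones had a median of only 8 counts over both total RNA libraries, against 838 for the large ones, so a moderate difference was not detectable for most of them. All small ones together held 603 counts in total RNA, against 182138 for the large ones. Their abundance was thus barely measured, and the split does not show that small snoRNAs were retained in poly(A) RNA. Whether these libraries recover short RNAs poorly was not tested. There were exceptions on both sides. The small snR128, of 126 bases and with 96 and 92 counts in total RNA, had -5.911, and the larger snR44, of 211 bases, only -0.825. snR44 lies inside a protein-coding gene, so its counts may include reads of that gene. The other large snoRNA inside a protein-coding gene, snR191, had -5.239. The large U3 RNA snR17a, which acts in 18S rRNA processing, had a log2 fold change of -10.32 (SE 0.11), snR30 one of -7.82 (SE 0.10) and the long snR86 one of -5.93 (SE 0.09). The signal recognition particle RNA SCR1 and the U2 spliceosomal RNA LSR1 had -9.68 and -8.74 (SE 0.11 for both).

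Mitochondrial mRNAs, which have no stable poly(A) tail in yeast, were reduced to unequal extents. COX3 and COX2, subunits of cytochrome c oxidase, had log2 fold changes of -9.95 and -9.05 (SE 0.26 and 0.24). OLI1, which encodes a subunit of ATP synthase (mitochondrial genome, 46723 to 46953), fell by only 1.62 (SE 0.10), with 262 and 379 counts in total RNA and 3488 and 3257 in poly(A) RNA. Parts of the rRNA precursor differed as well. The spacer ITS2-1 went from 13385 and 18931 counts to 10 and 7, and the 5′ external spacer ETS1-1 (chromosome XII, 457733 to 458432) from 14810 and 21307 to 3562 and 3411.

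Unequal retention of these untailed RNAs was set against 2 technical explanations. A copy of OLI1 in the nuclear genome is argued against, since the longest exact stretch of OLI1 in a nuclear chromosome of the reference was 17 bases, shorter than a read of 50. Capture through internal runs of A may contribute. The longest run of A had a Spearman's rho with the fold change of -0.19 (95% bootstrap interval -0.40 to 0.042), but length related to it more strongly (-0.70). With length taken out, a step chosen after that value was seen, the run related weakly to the fold change over 71 untailed RNAs with at least 20 counts in total RNA (partial Spearman's rho 0.228, 95% bootstrap interval 0.004 to 0.417). Some of the 71 overlap, as AI1 to AI4 do with COX1, or are copies, as ETS1-1 and ETS1-2 are. They are not independent, so bootstrap intervals over them are likely too narrow. ETS1-1 holds a run of 11 A and ITS2-1 a run of 3, but OLI1 also has only 3, and the mitochondrial 21S rRNA, with a run of 10, fell by 13.50. The 71 RNAs include rRNA and spacer features, and poly(A) RNA was also depleted of rRNA with a kit. For these features that step cannot be told apart from capture by runs of A, so their values do not decide it. Capture through internal runs of A stays open because the relation is weak and its interval nearly reaches 0. No biological explanation was tested, since the labels give no biological group beyond the RNA fraction.

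The decrease of long mRNAs was set against 3 explanations. Few counts in total RNA are argued against, because in the 1443 genes with most counts rho with length was -0.72 (95% bootstrap interval -0.75 to -0.69). GC content is argued against as the whole cause, since the weakest rho within 4 bins of GC content was -0.461. Loss of 5′ parts of long mRNAs before or during capture by the tail is a candidate explanation. Each gene of at least 1000 bp was divided into 4 parts of equal length. In the 3′ part, 9 of 10 overlap segments had a higher log2 ratio than the rest of that gene, with a mean difference of 0.499 (SE 0.16). The 4 segments in the 5′ part had -0.11 (SE 0.13), with 2 above the rest of their gene. The means of the 3′ and 5′ segments differed by 0.613 (exact two-sided permutation p = 0.0380). Genes with 5′ segments were at most 2028 bp long and those with 3′ segments up to 5046 bp, so position and length were not separated. The fewest counts of a segment in total RNA were 20. The segments also hold reads of the overlapping gene, and no biological explanation was tested.

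Coding genes rich in C were lower beyond the trend with length. In 4955 genes with at least 40 counts in total RNA, the length-corrected fold change had a median of 0.28 in the 1239 genes with least C and -0.51 in the 1239 with most, with rho -0.48 (95% bootstrap interval -0.50 to -0.45); cell wall genes had a median of 27.2% C. GC-dependent amplification or sequencing is argued against as the whole cause. The rho with the G fraction was 0.125 (95% bootstrap interval 0.10 to 0.15), the opposite sign, although amplification acts on both strands alike. The rho with GC content as a whole was -0.31, weaker than with C alone. A part played by GC content is not excluded, since the G value was not adjusted for C. For runs of A held by oligo-dT, the longest run had a rho of 0.14 with the length-corrected fold change (95% bootstrap interval 0.11 to 0.17). The A fraction had a rho of 0.29. With C fraction and length taken out, the partial rho of the longest run was 0.028. Base fractions sum to a fixed total, so taking out C also takes out part of the A content. That value therefore cannot decide on runs of A. The weakest rho with C within 4 bins of expression was -0.393, so expression level is argued against as well. What links C content to the fold change stays open, and no biological explanation was tested.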
